A study of Mus musculus with 2 samples.

How the data were processed

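Single-cell RNA was measured in pancreatic islets of 12-week-old female mice, in 1 library from Spop fl/fl mice (labelled control) and 1 library labelled as a beta-cell Spop knockout. Per the labels' protocols, islets were freed with collagenase, picked by hand, left to recover in RPMI medium, dispersed with trypsin and passed through dead-cell and debris removal before droplet capture with the 10x Genomics 3′ chemistry. The number of mice pooled in each library, the Cre driver and the deleted exons are not stated in the labels. The deposited values are raw UMI counts per gene and cell barcode, written by Cell Ranger 6.0.0 per the file headers. The reads were aligned to mm10 per the submitters' processing notes, which also name R 4.1.1 and Seurat 4.1.0. No step of theirs after counting is recorded in the count tables, and the rule by which barcodes were called cells is not stated there. Both tables hold 32285 features. Gene symbols and Ensembl identifiers were taken as the deposited tables pair them, and the positions of the 150 named genes were read from GENCODE mouse release 21 on the same build by identifier, with 150 matches.

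The control table held 7768 barcodes with 82541585 UMIs and the table labelled knockout held 10033 barcodes with 89977773 UMIs. Barcodes with at least 500 detected genes and at most 15% mitochondrial UMIs were kept. In the control library 517 barcodes had fewer genes and 647 had more mitochondrial UMIs, and in the library labelled knockout these numbers were 872 and 551. This left 6850 and 8842 cells, with medians of 8870 and 7638.5 UMIs and of 2963 and 2650.5 genes per cell. Doublets were scored per library with the Scrublet implementation of scanpy at an expected rate of 0.8% per 1000 barcodes. Its automatic thresholds, 0.550 and 0.652, called 0 cells in each library where 6.21% and 8.03% were expected, so doublet removal did not work and doublets remain among the cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and 15 neighbours led to Leiden clusters at resolution 1, without integration of the libraries. The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

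Clusters were named from 16 sets of marker genes. A marker counted as raised where its CPM (counts scaled to a common total) reached 10 and 2 times the lower quartile over clusters. Beta clusters had at least 3 raised beta markers and under 50% of the alpha, delta or acinar markers, and alpha and delta clusters had at least 50% of their own markers and fewer than 3 beta markers. A cluster stayed unnamed if another type's markers led its top 10 genes, or if 3 times its median UMIs fell below the library's median with none of its own markers among the top genes. These naming thresholds were set after the clusters had been seen. Beta clusters were 0, 2, 8, 9 and 10, alpha clusters were 4 and 12, the delta cluster was 11 and a mesenchymal cluster was 14. Low-UMI clusters with beta markers, a cluster with acinar genes and clusters with mixed endocrine markers were left unnamed. So was cluster 15, with endothelial and macrophage markers, which held 57 control and 82 knockout-labelled cells. Being unnamed, it did not count as another named class in the ranking of genes below.

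UMI counts were summed over the cells of a class in each library, and the sums were scaled to CPM with TMM factors (trimmed mean of M values) computed as edgeR does. The factors for the beta class were 1.04 for the control library and 0.959 for the library labelled knockout. Unscaled CPM would shift the median log2 ratio of all genes in the beta class by −0.12 relative to TMM, so ratios are given relative to the TMM scale. Each count has an exact 95% Poisson interval, each ratio an exact conditional 95% interval and each share of cells a Clopper-Pearson interval. With 1 library per genotype these intervals cover counting error only, cells of 1 library are not replicates, and no test of the genotype, p-value or number of changed genes was made. Where a library had 0 counts, a floor of 3 counts over the class sum was used.

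The gene lists, marker sets, cell filters, size limits and the first group of alternatives below were fixed before the data were examined. Named genes followed a rule. It took Spop, Spopl, Cul3, Ins1 and Ins2. In the beta class it took the first 15 genes higher and the first 15 lower in the library labelled knockout with a mean of at least 25 CPM and a 1.5-fold ratio, ranked by the interval bound nearest to no difference. It took up to 4 members of each list with the largest ratios at a mean of at least 10 CPM and an interval excluding no difference, and 8 genes on each side in the alpha class by the same ranking. Genes at least 5 times higher in another named class in both libraries were left out of the ranking, 3 in the beta class (Pyy, Sst, Rbp4) and 5 in the alpha class (S100a1, Iapp, Nupr1, Ins2, Ins1). A gene named outside this rule is said to be so. A few genes that the rule took count in the totals and list medians but are not reported here.

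For each of 32 gene lists, the median log2 ratio of members with a mean of at least 5 CPM was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and a percentile of at most 2.5 or at least 97.5 is described as standing apart. The percentile describes these 2 libraries. The interval of a list median comes from the ranks of its members and treats genes as independent, which they are not. Lists with fewer than 5 measured members got no median. The share of each cell's UMIs in a list was taken after thinning each cell at random to 5000 UMIs, which left out 197 control and 629 knockout-labelled beta cells with fewer.

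The steps were tested on simulated counts drawn from the real means and depths. In the beta class, 200 of 5565 simulated genes were changed, and the 95% interval covered the true ratio for 95.7% of unchanged genes and for 91.1% to 95.9% of genes at each simulated fold. All 30 genes named by the ranking had been changed, TMM factors differed from edgeR 4.0.16 by at most 3e-11, and 6.33% of unchanged lists stood apart by chance. A list shifted 1.25-fold was recovered at 1.26-fold. In the alpha class, where 5143 simulated genes reached that mean, 6.45% of unchanged lists stood apart and the same shift was recovered at 1.24-fold. Each gene was drawn independently, so variation between libraries and shared regulation of list members were not simulated.

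The alternatives fixed at the start were unscaled CPM, CPM without hormone and mitochondrial genes, median-of-ratios scaling, cells called by Scrublet kept, limits of 10% and 25% mitochondrial UMIs, at least 1500 genes per cell, a hormone gate in place of clusters, Leiden resolutions of 0.5 and 2, each cell weighted equally, thinning, and other expression minima. After seeing the data, further alternatives were added: removal of the highest Scrublet scores, each of the beta clusters 0, 9 and 10 alone, the mean within these clusters, and a beta class widened by unnamed clusters with beta markers. Counts along the Spop transcript were not used here, since the tables hold 1 total per gene.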

Results

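Islet cells of 12-week-old female mice were profiled by 3′ single-cell RNA sequencing in 2 libraries, 1 labelled Spop fl/fl (control) and 1 labelled beta-cell Spop knockout. SPOP is the substrate adaptor of a CUL3 ubiquitin ligase, and the series concerns the unfolded protein response of beta cells. The control library held 82541585 UMIs in 7768 barcodes and the library labelled knockout 89977773 UMIs in 10033 barcodes. After filtering, 6850 and 8842 cells remained, with a median of 8870 and 7638.5 UMIs per cell. There was 1 library per genotype, so every interval covers counting error only, and each difference is one between these 2 libraries and not a test of the genotype.

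Spop itself, the gene whose deletion separates the labels, was not lower in beta cells of the library labelled knockout. Spop (ENSMUSG00000057522, chromosome 11, 95414080 to 95493406 on mm10, plus strand, protein-coding) gave 70.2 CPM (UMI counts scaled to a common total; 95% interval 67.7 to 72.8, 3030 UMIs) in the beta class of the control library and 88.0 (85.6 to 90.5, 4974 UMIs) in that of the library labelled knockout, a log2 ratio of 0.33 (0.26 to 0.39). Within beta clusters 0, 9 and 10 the log2 ratio of Spop was −0.17, 0.18 and 0.04. In alpha cells, which keep the gene in a beta-cell deletion, Spop stood at 67.3 and 71.3 CPM, with a log2 ratio of 0.08 (−0.09 to 0.26). In delta cells it stood at 49.7 and 76.9 CPM. With each cell thinned to 5000 UMIs, at least 1 Spop UMI was seen in 29.2% of control and 32.9% of knockout-labelled beta cells, and in 28.3% and 29.8% of alpha cells. Without thinning, these shares were 55.9% and 56.2% in beta cells, at medians of 12210.5 and 11201 UMIs, and 36.3% and 32.2% in alpha cells, at 6966 and 5622. Between classes of 1 library, unscaled CPM were compared. In the library labelled control Spop was at 73.2 in the beta and 67.1 in the alpha class, 0.13 higher (log2, 0.01 to 0.24). In the library labelled knockout it was at 84.4 and 71.6, 0.24 higher (0.10 to 0.38). The TMM-scaled values of the control library given above lay closer together, at 70.2 and 67.3. A 3′ tag from a part of the transcript that is not deleted would not read the deletion, and the labels give neither the deleted exons nor the Cre driver, so these counts do not check the genotype and the directions that follow rest on the labels. Its paralog Spopl had a log2 ratio of −0.32 (−0.41 to −0.23), but 0.17, −0.32 and −0.07 within beta clusters 0, 9 and 10, and Cul3, the scaffold of the ligase, had one of −0.06 (−0.11 to −0.01).

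**Figure D1:**
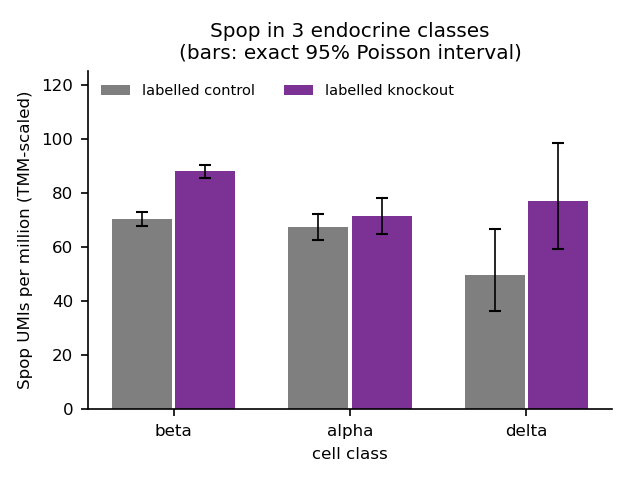
Spop CPM (TMM-scaled) in the beta, alpha and delta classes of the library labelled control (grey) and the library labelled knockout (purple), with exact 95% Poisson intervals as bars. In the beta class the values are 70.2 and 88.0, and in no class is the value of the library labelled knockout the lower one.

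Beta cells made up a larger and alpha cells a smaller part of the library labelled knockout. The beta class, defined by insulin and other beta-cell markers, held 2814 cells (41.1%, 39.9% to 42.3%) of the control library and 4513 (51.0%, 49.99% to 52.1%) of the library labelled knockout. Alpha cells, the glucagon producers, held 1419 (20.7%, 19.8% to 21.7%) and 987 (11.2%, 10.5% to 11.8%). Somatostatin-producing delta cells held 101 (1.47%) and 128 (1.45%), and mesenchymal cells 45 (0.657%) and 126 (1.43%). Unnamed clusters held 36.1% (34.9% to 37.2%) of control cells and 34.9% (33.9% to 35.9%) of the others, and among them clusters 1, 3, 5 and 6, which carry beta markers with few UMIs or with acinar genes, held 21.3% and 25.4%. Hand-picking, dead-cell removal and the cell filter can set such shares, and the order of the beta shares turned when at most 10% mitochondrial UMIs were allowed, to 49.3% in the control library and 46.0% in the library labelled knockout. With a hormone gate in place of clusters the beta shares were 51.0% and 76.6%. The alpha shares were 13.1% and 9.23% at most 10% mitochondrial UMIs and 27.5% and 13.7% with the hormone gate.

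The beta class was filled by different clusters in the 2 libraries. Cluster 0, led by the stress genes Hspa1b, Hspa1a, Gadd45a, Dnajb1 and Atf3, held 48.2% of the control beta class and 10.8% of the knockout-labelled one. Cluster 10 held 41.2% and 10.4%, cluster 9 held 7.14% and 29.4%, cluster 2 held 2.42% and 29.98%, and cluster 8 held 1.14% and 19.4%. Every beta-class value below is therefore a sum over clusters 0 and 10 in the control library, for the most part, set against a sum led by clusters 2, 8 and 9 in the library labelled knockout. Clusters 0, 9 and 10 held at least 100 cells of both libraries, so that a ratio within each could be taken. Top genes included Crybb3 and Chgb in cluster 2, Enpp2 and Socs2 in cluster 8, G6pc2, Mafa and Prlr in cluster 9, and Rassf10, Gsto1 and Robo1 in cluster 10. Some ductal markers were also raised in clusters 2 and 8, and some pancreatic polypeptide cell markers in clusters 8 and 9. The median mitochondrial share was 0.70% in cluster 0 and 4.98% in cluster 9.

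Within the beta class, the library labelled knockout had more RNA for insulin, secretory granule cargo and glucose sensing and less for the integrated stress response, heat shock and p53 targets. Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476, plus strand) stood at 10148 CPM in the control library and 48700 in the library labelled knockout, 4.80-fold higher with a log2 ratio of 2.26 (2.26 to 2.27). Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381, minus strand), the other mouse insulin gene, was 1.57-fold higher with a log2 ratio of 0.65. Insulin RNA was also higher in the alpha class of the library labelled knockout, at log2 ratios of 2.35 (2.32 to 2.39) for Ins1 and 1.05 (1.04 to 1.06) for Ins2, in a class whose cells do not make insulin. Within cluster 0 the log2 ratio of Ins1 was −0.10 and that of Ins2 was −0.79, within cluster 9 they were 0.94 and 0.16, and within cluster 10 they were 0.72 and 0.14.

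Among the 15 genes higher in the library labelled knockout by the size ranking, Fmo1, a flavin-containing monooxygenase, was 28.4-fold higher, from 2.85 to 81.1 CPM (log2 ratio 4.83, 4.57 to 5.10). Enpp2, which encodes autotaxin, was 9.02-fold higher, and Gpx3, a secreted glutathione peroxidase, 8.84-fold. Chgb, the granule protein chromogranin B, was 5.33-fold higher, Ddc, the decarboxylase of L-DOPA and 5-hydroxytryptophan, 4.87-fold, and Txnip, a glucose-induced thioredoxin-binding protein, 5.59-fold. Crybb3, a crystallin, was 9.46-fold higher, the noncoding RNA Snhg11 8.21-fold, Rnf150 6.08-fold, the autophagy protein Wipi1 5.78-fold and the sorting receptor Sorl1 5.25-fold. The complement gene C1qa, a macrophage marker, was 10.6-fold higher, and Tspan8, a marker of pancreatic polypeptide cells, 10.8-fold. Most but not all measured markers of other cell types were higher in this class: 4 of 4 measured macrophage markers summed to 12.7 CPM in the control library and 74.4 in the library labelled knockout, and 4 of 4 pancreatic polypeptide cell markers to 563 and 1742. The 4 measured delta and 5 ductal markers were higher as well, with median log2 ratios of 1.21 and 0.86, as were 5 of 7 alpha markers, with a median of 0.28, whereas the 1 acinar and the 1 B-cell marker were lower, at −1.87 and −1.19, and 1 of 2 glial markers was higher.

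The 15 genes lower in the library labelled knockout were led by Lmo4, a LIM-domain cofactor usually kept low in beta cells, which was 4.29-fold lower, from 50.3 to 11.7 CPM (log2 ratio −2.10, −2.23 to −1.98). The guidance receptor Robo1 was 3.93-fold lower, the inducible heat shock protein Hspa1b 3.50-fold, the glucose transporter Slc2a1 2.67-fold, the metallothionein Mt2 2.46-fold and the transcription factor Atf3, induced by many stresses, 2.24-fold. Id2, an inhibitor of helix-loop-helix factors, was 2.52-fold lower, Msln 2.62-fold, the glutathione transferase Gsto1 2.504-fold, Rhou 2.45-fold, Rassf10 2.40-fold, the glucuronosyltransferase Ugt2b34 2.34-fold, Rasgef1b 2.32-fold and the ribonuclease Rnase4 2.18-fold. Gm42418, a locus that overlaps ribosomal RNA sequence, was 2.73-fold lower. Within cluster 0, 29 of the 30 genes kept the direction they had in the whole class, with Ins1 the exception, and within clusters 9 and 10 all 30 did. A ratio of at least 1.5-fold was kept by 22, 27 and 22 of them within clusters 0, 9 and 10. Txnip had log2 ratios of 0.14 and 0.52 in clusters 0 and 10, Atf3 of −0.28 and −0.06, and Hspa1b was at −0.15 in cluster 10.

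**Figure D2:**
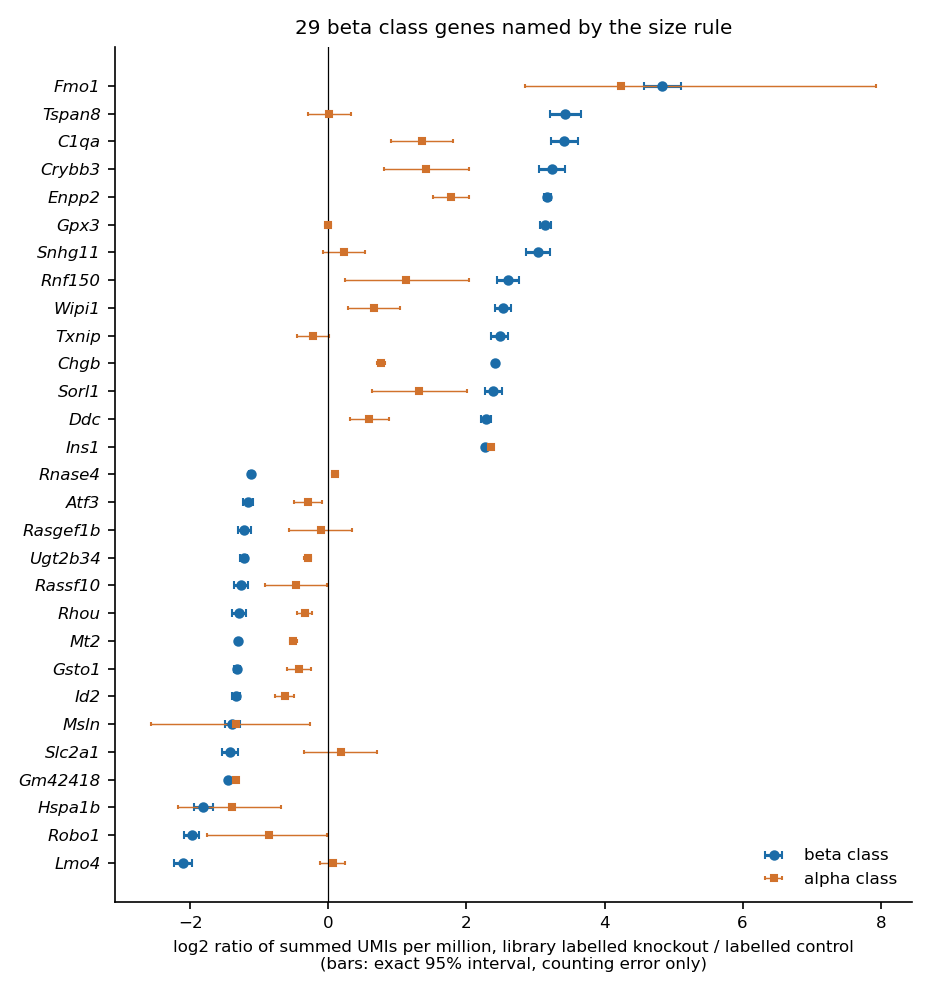
Log2 ratio of summed CPM, library labelled knockout over library labelled control, for 29 genes named by size in the beta class, with circles for the beta class, squares for the alpha class and bars for exact 95% counting intervals. Fmo1, Ins1, Gm42418, Msln and Hspa1b lie on the same side of 0 in both classes with intervals that exclude 0, whereas Gpx3 and Tspan8 lie near 0 in the alpha class.

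Targets of ATF4 and CHOP, the transcription factors of the PERK arm that act on amino acid supply and cell death, were lower in the beta class of the library labelled knockout. Of 33 measured members 30 were lower and 3 higher, the median log2 ratio was −0.46 (−0.62 to −0.30), and it lay at percentile 0 of the random lists. Trib3, a pseudokinase that feeds back on this arm, had a log2 ratio of −0.80 (−0.85 to −0.75), Slc3a2, a heavy chain of amino acid transporters, of −0.77, Gpt2, an alanine transaminase, of −0.82 and Atf3 of −1.16. The list also holds the 2 regulators themselves. Ddit3, which encodes CHOP, went from 1454 to 907.6 CPM (log2 ratio −0.68, −0.70 to −0.66), and Atf4 had a log2 ratio of −0.63. Within clusters 0, 9 and 10 the list medians were −0.26, −0.37 and −0.17.

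Targets of XBP1, the factor of the IRE1 arm that builds up translocation and transport in the endoplasmic reticulum, lay on the other side. Of 25 members 21 were higher, with a median of 0.24 (0.12 to 0.32) at percentile 100, among them Edem2 at 0.77, Arfgap3 at 0.72, the oligosaccharyltransferase subunit Ostc at 0.66 and the translocon subunit Sec61b at 0.61. Within cluster 0 the XBP1 median was −0.23, within cluster 9 it was 0.31 and within cluster 10 it was 0.02, so that its direction depended on the cluster. ATF6 targets and chaperones did not stand apart in the whole class, with a median of 0.09 at percentile 97.49, 14 of 20 members higher, Fkbp2 at 0.86, Ppib at 0.37 and Dnajc3 at 0.32. Their median turned to −0.03 with unscaled CPM and to −0.02 with each cell weighted equally. Within clusters the list stood apart on opposite sides, at −0.32 in cluster 0 (percentile 0, 17 of 20 lower), 0.22 in cluster 9 (percentile 99.96, 19 of 20 higher) and 0.07 in cluster 10 (percentile 98.8). A central member, Hspa5 (the chaperone BiP), was lower in the whole class, at −0.50 (−0.51 to −0.49), and within clusters 0, 9 and 10 it was at −0.56, 0.21 (0.16 to 0.27) and 0.03. UPR sensors and transcription factors as a list had a median of −0.06 at percentile 46.1, with Creb3l2 at 0.76 and the eIF2α phosphatase subunit Ppp1r15b at −0.71. ER-associated degradation had a median of −0.08 at percentile 36.4, with Edem2 at 0.77, Aup1 at −0.47, Herpud2 at −0.38 and Derl1 at −0.37. Oxidative protein folding had a median of 0.14 at percentile 97.1, with the oxidases Ero1lb at 0.91, Qsox1 at 0.88 and Ero1l at −0.74 and the isomerase Pdia5 at 0.75. Under alternatives added after seeing the data, Ero1lb turned to as low as −0.13, and Qsox1 and Pdia5 fell to as low as 0.16 and 0.10. Vesicle transport between ER and Golgi had a median of −0.11 at percentile 24, with Sec24d at 0.47, Surf4 at 0.38, Kdelr2 at −0.46 and Copb2 at −0.42. Within cluster 0 these last 3 lists stood apart as lower, at −0.21, −0.28 and −0.31, and within clusters 9 and 10 they did not stand apart.

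Genes of the mature beta cell were higher in the library labelled knockout as groups, yet not within clusters 0, 9 and 10, where some turned to lower. The clusters were made from the same expression values, and G6pc2, Mafa, Slc2a2 and Ffar1 are among the top genes of cluster 9. Small ratios within clusters are therefore in part built in, and clusters 2 and 8 were not compared. Prohormone processing and granule cargo had 18 of 20 members higher and a median of 0.60 (0.30 to 0.87) at percentile 100, with Chga (chromogranin A) at 1.63 and Resp18 at 1.78. Beta cell transcription factors had 14 of 16 members higher and a median of 0.54 (0.29 to 0.75) at percentile 100, with the insulin gene activators Mafa at 0.85 and Pdx1 at 0.72, Mnx1 at 0.90 and Mlxipl at 0.75. Glucose sensing and exocytosis had 19 of 23 higher and a median of 0.55 (0.23 to 0.84) at percentile 100, with the glucose transporter Slc2a2 at 1.22, G6pc2 at 1.83, the fatty acid receptor Ffar1 at 1.19 and the ion channel Trpm5 at 1.02. Within clusters 0, 9 and 10 the medians were −0.07, 0.02 and 0.01 for prohormone processing, −0.02, −0.05 and −0.06 for transcription factors and −0.05, −0.03 and −0.07 for glucose sensing. Mafa turned there to −0.13, −0.63 (−0.67 to −0.58) and −0.90 (−1.05 to −0.75), Pdx1 to −0.15, −0.04 and −0.15 and Ffar1 to −0.29, −0.29 and −0.23, and Slc2a2 was at 0.43, −0.27 and −0.32. The list of immature or dedifferentiated beta cells stood apart at percentile 100 with a median of 1.32 (−0.30 to 2.67), but only 4 of 7 measured members were higher. Within clusters 0, 9 and 10 its medians were 0.45, 0.35 and 0.54, which stood apart. Pyy was at 2.67, Npy at 1.95 and Rbp4 at 1.39, of which Pyy and Rbp4 also mark pancreatic polypeptide and delta cells, and Npy was at −1.73, 0.38 and −0.85 within clusters 0, 9 and 10. Genes usually repressed in beta cells had 3 measured members and no median: Lmo4 as above, Cat at −1.06 and Zyx at −0.65.

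Cytosolic heat shock genes and p53 targets were lower in the beta class of the library labelled knockout. Heat shock had 13 of 14 members lower and a median of −0.50 (−0.79 to −0.18) at percentile 0, with Hspa1a at −1.91, Dnajb1 at −0.79 and Hspa8 at −0.70, in a class whose control cells came largely from the cluster led by Hspa1a and Hspa1b. Within cluster 0 the heat shock median was −0.23 at percentile 1.36, and within clusters 9 and 10 the list did not stand apart, at 0.01 and 0.05. Targets of p53 and cell death genes had 13 of 16 lower and a median of −0.60 (−0.89 to −0.05) at percentile 0, with the cell cycle inhibitor Cdkn1a at −0.89, Gadd45a at −0.89, Trp53inp1 at −0.95 and Zmat3 at −0.92. Gadd45a, a top gene of cluster 0, shrank to −0.22 under an alternative added after seeing the data. Within clusters 0 and 10 the p53 medians were −0.38 and −0.24, and within cluster 9 the list no longer stood apart, at −0.09 and percentile 5.63 with 10 of 16 lower.

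Immediate early, interferon and antigen presentation genes were higher. Of the immediate early and dissociation list 12 of 16 were higher, with a median of 0.63 (−0.48 to 2.01) at percentile 100, led by Egr1 at 2.22, Fos at 2.17 and Fosb at 2.14. Within clusters 0, 9 and 10 its medians were −0.15, 0.72 and 0.43. Interferon response had 8 of 10 higher and a median of 0.80 (−0.02 to 1.01) at percentile 100, with Usp18 at 1.51, Bst2 at 1.01, Gbp7 at 0.86 and Irf1 at 0.75. Within clusters 0 and 10 the interferon medians were 0.47 and 0.39, and within cluster 9 the list did not stand apart, at 0.16 and percentile 90.2. MHC class I presentation had 11 of 11 higher and a median of 0.85 (0.27 to 1.23) at percentile 100, with the class I genes H2-Q7 at 1.73 and H2-T23 at 1.23 and the immunoproteasome subunits Psmb9 at 1.22 and Psmb8 at 1.09. Within clusters 0, 9 and 10 the MHC class I medians were 0.60, 0.22 (−0.07 to 0.81) and 0.62, with 3, 3 and 1 of 11 members lower. The macrophage markers given above moved the same way in this class. NF-kB and inflammatory genes had a median of −0.16 at percentile 24.6, with Il1r1, Cxcl16 and Sod2 at −0.16 each.

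Lactogen response genes, which prolactin and human growth hormone induce in islets through the prolactin receptor and STAT5, had the highest list median of the 30 lists that could be measured. Of 8 measured members 7 were higher, the median was 2.23 (−0.23 to 5.39) and it lay at percentile 100. Neb was 42.0-fold higher, from 26 to 1430 UMIs, Cish, a STAT5-induced feedback inhibitor, 11.4-fold, Matn2 6.83-fold and Wipi1 5.78-fold, while Ccnd2 had a log2 ratio of −0.23. Chosen after their values were seen, Prlr (the prolactin receptor) was 3.83-fold higher, Socs2 3.798-fold and Ivd 2.47-fold. Of the serotonin synthesis genes, also named after their values were seen, Tph1 had 0 UMIs in the control beta class and 484 in the knockout-labelled one, at least 123-fold higher if the control class is set at the floor of 3 counts (the exact 95% interval of the log2 ratio begins lower, at 6.64), and Tph2 had 3 and 170 UMIs, a log2 ratio of 5.44 (3.86 to 7.73). Within clusters 0, 9 and 10 the list medians were 0.18, 2.06 (1.24 to 4.58) and 0.74, over 5, 10 and 7 measured members. In cluster 0 the list did not stand apart, at percentile 95.1. Mitochondrially encoded genes were higher as well, 13 of 13 (with unscaled CPM mt-Nd2 and mt-Nd3 turned to −0.07 and −0.06), with a median of 0.33 (0.22 to 0.71) at percentile 99.99, mt-Nd4l at 1.10, mt-Nd6 at 0.79, mt-Nd5 at 0.71 and mt-Co2 at 0.56. The median mitochondrial share of UMIs per beta-class cell was 1.33% in the control library and 2.02% in the library labelled knockout, and the list medians within clusters 0, 9 and 10 were −0.11, −0.19 and −0.23. Glucose-responsive ChREBP targets had 7 of 9 members higher and a median of 0.29 (−0.15 to 1.83) at percentile 97.8, led by Txnip and G6pc2, but did not stand apart within clusters 0, 9 and 10, at 0.11, 0.09 and 0.05.

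The remaining lists did not stand apart in the beta class. Genes of described SPOP substrates had a median of −0.01 at percentile 66.1 with 9 of 19 members higher, the BET protein gene Brd2 at −0.75, Pdx1 at 0.72, Ddit3 at −0.68 and Fasn at −0.46. These are RNA values, and the substrate proteins were not measured. The Hedgehog pathway had 3 measured members and no median, with Ccnd1 at −0.16. NRF2 and antioxidant genes had a median of −0.17 at percentile 4.51, with Gpx1 at 1.00 and Mt2 at −1.30. Cell cycle genes had 8 of 8 lower and a median of −0.26 at percentile 3.14, with Pcna at −0.87, Stmn1 at −0.49, Mcm7 at −0.27 and Tyms at −0.25. Glycolysis had a median of −0.11 at percentile 26.4, with Pfkp at 0.81, Pkm at 0.35 and Pgk1 at −0.62. The nuclear genes of oxidative phosphorylation had a median of −0.02 at percentile 84.7, with Cox6a2 at −0.83, Atp5b at −0.49, Ndufv1 at −0.49 and Ndufa12 at −0.39. Ribosomal proteins had a median of −0.08 at percentile 18.2, with Rpl12 at −0.51, Rps2 at −0.48, Rpl7a at −0.37 and Rps18 at −0.35, and the proteasome one of −0.13 at percentile 10.2, with the base subunits Psmc4 and Psmc2 at −0.53 each. Cholesterol synthesis had a median of −0.05 at percentile 40.1, with Msmo1 at −0.70, Lss at −0.53 and Fdps at −0.50. Fatty acid synthesis had a median of 0.09 at percentile 85.7, with Acly at 0.67, Me1 at 0.45, Srebf1 at 0.34 and Fasn at −0.46, and autophagy and lysosome genes one of 0.00 at percentile 72.5, with Gabarapl2 at 0.39, Ctsb at −0.31 and Sqstm1 at −0.22. In the mean within clusters 0, 9 and 10, Acly turned to −0.065, Srebf1 to −0.26, Pkm to −0.12 and Mcm7 to 0.050. In all, 11 lists stood apart as higher and 3 as lower, 16 did not stand apart and 2 could not be measured. On simulated counts 6.33% of unchanged lists stood apart by chance. Those counts were drawn gene by gene, with no variation between libraries and no shared regulation of list members. How often real lists would stand apart without an effect of genotype is therefore not known.

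**Figure D3:**
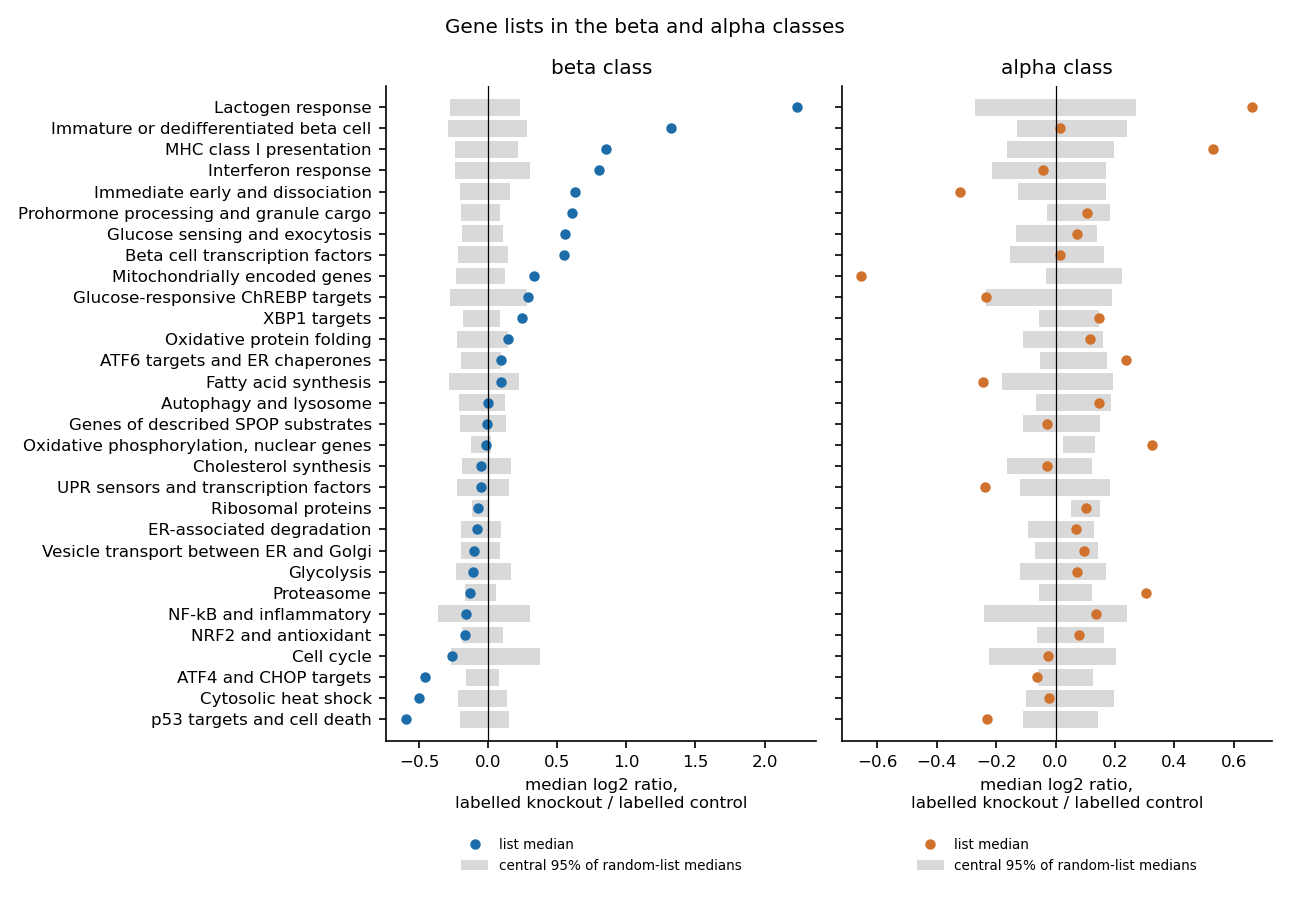
Median log2 ratio, library labelled knockout over library labelled control, of each gene list in the beta class (left) and the alpha class (right), with grey bands for the central 95% of medians of expression-matched random lists; the axes of the panels differ in scale. Lactogen response lies at 2.23 in the beta class and 0.66 in the alpha class, whereas ATF4 and CHOP targets lie at −0.46 and −0.06.

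**Figure D4:**
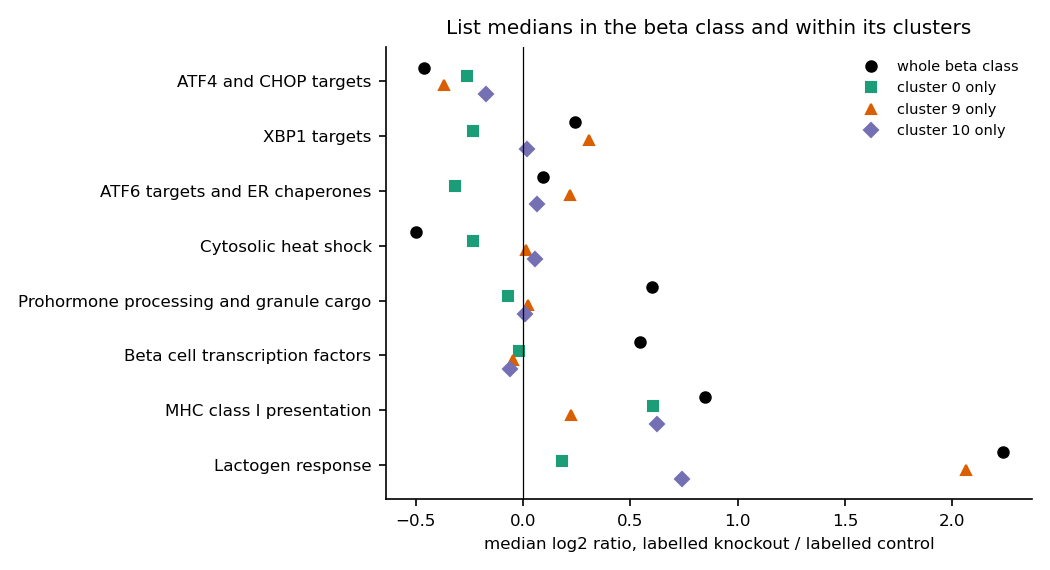
Median log2 ratio, library labelled knockout over library labelled control, of 8 gene lists in the whole beta class (black circles) and within clusters 0 (squares), 9 (triangles) and 10 (diamonds). ATF4 and CHOP targets lie below 0 in all 3 clusters, at −0.26, −0.37 and −0.17, whereas prohormone processing and beta cell transcription factors lie between −0.07 and 0.02 there.

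Per beta cell, a smaller share of UMIs came from ATF4 and CHOP targets and a larger one from insulin in the library labelled knockout. After thinning to 5000 UMIs, the median share of ATF4 and CHOP targets was 0.76% of a cell's UMIs in the control library (quartiles 0.56% and 0.92%, 2617 cells) and 0.50% in the library labelled knockout (0.24% and 0.78%, 3884 cells). Ins1 and Ins2 together took a median of 5.16% (1.56% and 13.3%) and 11.2% (4.76% and 23.4%). The medians for ATF6 targets were 0.62% and 0.60%, and for XBP1 targets 0.48% (0.38% and 0.56%) and 0.50% (0.40% and 0.62%).

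**Figure D5:**
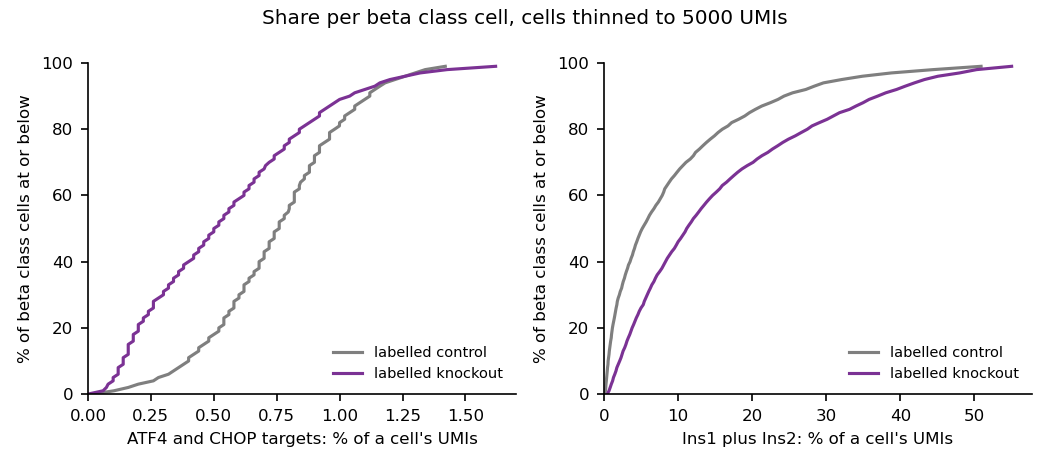
Percent of beta-class cells at or below each share of UMIs, for ATF4 and CHOP targets (left) and Ins1 plus Ins2 (right), in cells thinned to 5000 UMIs of the library labelled control (grey) and the library labelled knockout (purple). The medians are 0.76% and 0.50% on the left and 5.16% and 11.2% on the right.

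Alpha cells, outside a beta-cell deletion, were compared in the same way. The class pooled cluster 4, with 399 control and 185 knockout-labelled cells, and cluster 12, with 1020 and 802. Their median mitochondrial shares were 1.40% and 3.06%, and ratios within these clusters were not taken. The alpha class held insulin RNA, with Ins1 at 810 CPM in the control library and 4137 in the library labelled knockout. A gene that is abundant in beta cells can therefore be higher in this class without a difference in alpha cells. In the alpha class MHC class I presentation was higher as in beta cells, with a median of 0.53 (−0.05 to 1.09) at percentile 100 and B2m, the class I light chain, at 1.09 (0.99 to 1.20), and lactogen response was higher with a median of 0.66 (−0.02 to 2.18) over 5 measured members. ATF4 and CHOP targets had a median of −0.06 (−0.23 to −0.02) at percentile 2.04, so that the beta minus alpha difference of the medians was −0.40. That difference carries the mix of beta clusters, within which the beta medians were smaller, at −0.26, −0.37 and −0.17 in clusters 0, 9 and 10. Heat shock, at −0.02, and interferon response, at −0.04, did not stand apart. Nuclear genes of oxidative phosphorylation were higher, 72 of 77 with a median of 0.32 (0.26 to 0.39), as were proteasome genes at 0.30 (0.18 to 0.36) and ATF6 targets at 0.24 (0.17 to 0.37). UPR sensors and transcription factors were lower, at −0.24, as were p53 targets at −0.23, fatty acid synthesis at −0.25, genes repressed in beta cells at −0.32, immediate early genes at −0.32 and all 13 mitochondrially encoded genes, with a median of −0.65 (−0.82 to −0.48) and mt-Nd2, mt-Cytb, mt-Atp6 and mt-Nd3 at −0.88, −0.82, −0.80 and −0.82. The median mitochondrial share per alpha cell was 3.29% in the control library and 1.92% in the library labelled knockout. In all, 5 lists were higher, 7 lower and 19 not apart. Whether the 2 classes differ was not tested, since each ratio comes from 1 pair of libraries.

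Single genes ranked in the alpha class included some that also lay apart in the beta and delta classes, and the share of these counts that came from RNA of beta cells was not estimated. Spp1 (osteopontin) was higher by a log2 ratio of 1.97 (1.85 to 2.09), Enpp2 by 1.78, Gm10076 by 0.99, the glutathione transferase Gstp1 by 1.04, Bst2 by 0.99 and the ribonuclease Rnase1, an acinar marker, by 1.51. On the lower side stood Gm42418 at −1.34, the mitochondrial leucyl-tRNA synthetase gene Lars2 at −1.07, Smad7 (an inhibitor of TGF-beta signalling) at −0.92 and AY036118 at −0.83. Across 4720 genes measured in 3 classes, 10 were at least 1.5-fold higher in the library labelled knockout in the beta, alpha and delta classes alike (among them Cldn7, Chgb, Nucb2, Gatm, Aga, Gm10076, B2m, Enpp2 and Spp1, of which Cldn7, Nucb2, Gatm and Aga are named after their values were seen) and 3 were lower (Gm42418, Lars2 and AY036118). Across 4847 genes, which are not independent replicates, the log2 ratios of the beta and alpha classes had a Pearson correlation of 0.30 and a Spearman correlation of 0.26. In the delta class, 6 lists stood apart as higher and 2 as lower. Lactogen response had a median of 1.32 (−0.09 to 2.02) and MHC class I presentation one of 0.45 (−0.38 to 0.99). Heat shock was at −0.33 (−0.64 to 0.0035) and ATF4 and CHOP targets at −0.11 (−0.19 to 0.02). Each of these intervals includes 0.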

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

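The tests of the Spop counts, of the Cre driver and of handling were chosen only after the results they bear on had been seen, whereas those of cluster mix, RNA of other cells and depth were written down before their values were seen, though after the clusters themselves. Differences between the beta and alpha classes named here were not tested, since each ratio comes from 1 pair of libraries.

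Spop tags were not lower in the beta class of the library labelled knockout, at a log2 ratio of 0.33 (0.26 to 0.39). Intact cells mixed into the class could dilute a deletion but not raise Spop, and the lowest ratio within beta clusters 0, 9 and 10 was −0.17 (−0.38 to 0.04) in cluster 0, while clusters 2 and 8 were not measured. An exchange of the 2 libraries would put Spop of beta cells below that of alpha cells in the library labelled control. There it was 0.13 (log2) above with unscaled CPM, and at 70.2 against 67.3 CPM with TMM scaling. Neither value decides, because both need tags that read the deleted exons, and a count outside them, the third candidate explanation, leaves the total at 0.33 whatever the genotype. These explanations and the labels as given cannot be told apart from totals per gene.

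Lactogen response genes were higher in the beta class of the library labelled knockout, with a list median of 2.23. A different mix of beta clusters is argued against as the whole cause by the median of 2.06 (1.24 to 4.58) within cluster 9. Cluster 0, at 0.18, missed the bound set beforehand and did not stand apart (percentile 95.1), and cluster 10 was at 0.74. These medians were taken over 5, 10 and 7 measured members in clusters 0, 9 and 10, against 8 in the whole class. The mix may account for a part, but medians over unlike members cannot show how much. RNA or doublets of another cell class are argued against, since 1 of 8 measured members (Ccnd2) was higher than in the beta class in any of the compared clusters, which left out the beta-marker clusters 1, 3, 5 and 6. A lactogen signal from the Cre driver line may produce the same 2.23, since some beta-cell drivers carry a human growth hormone minigene. Without a library that has the driver and intact Spop this cannot be told apart from the loss of Spop. The hypothesis that Spop loss itself raises these genes stays open and untested.

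ATF4 and CHOP targets were lower in the beta class of the library labelled knockout, with a list median of −0.46 (−0.62 to −0.30). Unequal weight of deeper cells in the sums is argued against by −0.41 (−0.54 to −0.21) after thinning. Random thinning keeps each cell's expected composition, so it cannot show whether cells of different depth differ in other ways. A different mix of clusters is argued against as the whole cause by −0.37 (−0.49 to −0.24) within cluster 9, while cluster 10, at −0.17, missed the bound set beforehand and cluster mix may account for a part. Handling that acts on every islet cell alike cannot be told apart, because the list was also lower in the alpha class, at −0.063 (−0.23 to −0.02, percentile 2.04), an interval that those of clusters 0 and 10 overlap, while handling to which beta cells alone respond and the cluster led by heat shock genes in the control library also stay open. Lower ATF4 output after loss of Spop is a hypothesis, with 1 library per genotype and Spop counts that do not check the label.

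These results stood out because the beta and alpha classes lay on opposite sides of no difference. For mt-Nd4l the log2 ratios were 1.10 in the beta class and −0.47 in the alpha class. For mt-Nd5 they were 0.71 and −0.63. For mt-Co2 they were 0.56 and −0.65. For the acinar ribonuclease Rnase1 they were −1.87 and 1.51. The mitochondrially encoded list had medians of 0.33 in the beta class and −0.65 in the alpha class, but within beta clusters 0, 9 and 10 they were −0.11, −0.19 and −0.23, on the same side as alpha. The immediate early and dissociation list had medians of 0.63 and −0.32, and within beta clusters 0, 9 and 10 they were −0.15, 0.72 and 0.43.

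In cells outside the compared classes, lactogen response stood out at a median of 1.57 (−0.47 to 2.08) in the beta-marker clusters left unnamed, at percentile 100 of random lists. The mix of these pooled clusters differed between the libraries.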

How the results depend on the processing

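The single-cluster settings, the mean within clusters, the removal of high Scrublet scores and the widened beta class were chosen after seeing the data. Keeping cells called by Scrublet moved nothing, since none were called. Under the 12 planned settings all 30 size-ranked genes kept a 1.5-fold ratio in the same direction and 13 or 14 of the 14 lists that stood apart still did so on the same side (12 with list members at 20 CPM or more). The beta minus alpha difference for ATF4 and CHOP targets stayed between −0.52 and −0.26. None of these settings held the mix of beta clusters fixed, and that difference was not computed within clusters. The beta medians of this list were −0.26, −0.37 and −0.17 within clusters 0, 9 and 10, against −0.06 in the alpha class. The cause of the changes below was not tested, and within a cluster fewer cells with like expression are compared by construction.

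With unscaled CPM, Spop was at 0.21, mt-Nd2 at −0.067, mt-Nd3 at −0.061 and ATF6 targets at −0.027. With each cell weighted equally, Spop was at 0.20, ATF6 targets at −0.017 and XBP1 targets at 0.091. At Leiden resolution 0.5, Cul3 was at 0.0090. Of the 30 size-ranked genes, 16 were shared with a minimum of 10 CPM and 11 with a minimum of 100 CPM, which only 11 of them reach.

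A 1.5-fold ratio in the same direction was kept by 22, 27 and 22 of the 30 genes within clusters 0, 9 and 10. Within cluster 0, Spop was at −0.17 and 6 of 14 lists stood apart on the same side, ATF4 targets at −0.26 among them. XBP1 targets, at −0.23, stood apart there on the other side (percentile 0.33), and ATF6 targets were at −0.32 (percentile 0). Not apart were prohormone processing at −0.072, beta cell transcription factors at −0.019, glucose sensing at −0.054, mitochondrially encoded genes at −0.11 and immediate early genes at −0.15. Heat shock, at −0.23 in cluster 0, still stood apart there. Within cluster 9, Spop was at 0.18 and 6 lists stood apart on the same side. ATF6 targets, not apart in the whole class, were at 0.22 (percentile 99.96). Mitochondrially encoded genes, at −0.19, stood apart on the other side (percentile 1.075). Not apart were prohormone processing at 0.022, beta cell transcription factors at −0.048, glucose sensing at −0.029, heat shock at 0.013, p53 targets at −0.091 and interferon response at 0.16. Within cluster 10, Spop was at 0.039 and 7 lists stood apart on the same side, ATF4 targets at −0.17 among them. Mitochondrially encoded genes, at −0.23, stood apart on the other side (percentile 0.205). Not apart were XBP1 targets at 0.019, prohormone processing at 0.012, beta cell transcription factors at −0.062, glucose sensing at −0.075 and heat shock at 0.054.

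In the mean within these clusters, Spop was at 0.017 and 7 lists stood apart on the same side. Whether or not they stood apart, ATF4 targets were at −0.27, XBP1 targets at 0.028, ATF6 targets at −0.0041, prohormone processing at −0.025, beta cell transcription factors at −0.0094 and mitochondrially encoded genes at −0.15. Of the named genes that were followed, 123 moved out of the 95% interval of their whole-class ratio there without turning, 16 turned and 6 stayed. Those that turned were Ins2 at −0.16, Ero1lb at −0.13, Mafa at −0.55, Pdx1 at −0.11, Slc2a2 at −0.056, Ffar1 at −0.27, Npy at −0.73, Pkm at −0.12, mt-Co2 at −0.060, Acly at −0.065, Srebf1 at −0.26, Mcm7 at 0.050, mt-Nd2 at −0.44, mt-Cytb at −0.32, mt-Atp6 at −0.27 and mt-Nd3 at −0.46.

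The beta share of the control library was 49.3% at most 10% mitochondrial UMIs, 56.1% at 1500 genes, 23.7% at Leiden 0.5, 43.1% at Leiden 2, 51.0% with the hormone gate and 62.3% in the widened class. That of the library labelled knockout was 46.0% at 10% and 48.6% at 25% mitochondrial UMIs, 70.9% at 1500 genes, 30.9% at Leiden 0.5, 76.6% with the hormone gate and 76.48% widened. The alpha share was 13.1% and 9.23% in the 2 libraries at 10% mitochondrial UMIs, and 27.5% and 13.7% with the hormone gate. The per-cell share of ATF4 and CHOP targets, as a ratio of medians, was 0.629 at 8000 UMIs.

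Depth limits the delta class most, where counting alone spread log2 ratios by an SD of 0.28, against 0.10 in the alpha and 0.04 in the beta class.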

Other observations

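All values in this part come from comparisons chosen after the data had been seen, apart from the gene lists themselves.

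Clusters with beta markers that were left unnamed for few UMIs or acinar genes, clusters 1, 3, 5 and 6, held 1456 control cells and 2249 knockout-labelled cells, at medians of 2169.5 and 1630 UMIs. Their mix differed between the libraries, with 596 control and 459 knockout-labelled cells in cluster 3, and 249 and 633 in cluster 6. The ratios that follow were taken over the pooled clusters and so compare different mixes. ATF4 and CHOP targets had a median log2 ratio of −0.27 at percentile 0.57 with 23 of 31 members lower, heat shock genes one of −0.51 with 14 of 14 lower, and p53 targets one of −0.65 with 14 of 15 lower. MHC class I presentation had a median of 0.86 with 11 of 11 higher. Fmo1 had a log2 ratio of 3.59 (2.76 to 4.57), Enpp2 of 3.08, Crybb3 of 2.63, Chgb of 1.93, Prlr of 1.57 and Neb of 2.08, and Tph1 had 0 UMIs in the control library and 28 in the library labelled knockout. Ins2, by contrast with the beta class, was at −0.75 (−0.76 to −0.75), Ins1 at 0.16, and beta cell transcription factors did not stand apart, with a median of −0.17. Spop was at 0.34 (0.05 to 0.63).

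Some lists near 0 in the whole beta class lay apart within a cluster. Cholesterol synthesis genes had 15 of 15 members lower within cluster 0, with a median of −0.58 (−0.78 to −0.20) at percentile 0, and 14 of 18 lower within cluster 10, with a median of −0.27, whereas within cluster 9 11 of 18 were higher, with a median of 0.14 at percentile 95.1, against −0.05 in the whole class. Ribosomal protein genes had 68 of 80 members lower within cluster 9, with a median of −0.15 (−0.18 to −0.11) at percentile 0, and a median of −0.10 at percentile 1.67 within cluster 10, whereas in cluster 0 the median of −0.01 lay at percentile 100, above the random lists. Nuclear genes of oxidative phosphorylation stood apart as lower within clusters 0 and 10, at −0.20 and −0.11, but not within cluster 9, at 0.03. Glycolysis did so within clusters 9 and 10, at −0.18 and −0.21, the proteasome within cluster 0, at −0.21, and fatty acid synthesis within cluster 10, at −0.24. Immediate early and dissociation genes had a median of 0.72 (0.11 to 0.88) within cluster 9, 0.43 within cluster 10, −0.15 within cluster 0 and −0.33 in the unnamed beta-marker clusters. The MHC class I presentation median lay above 0 within clusters 0, 9 and 10, at 0.60 (−0.06 to 1.11), 0.22 (−0.07 to 0.81) and 0.62 (0.08 to 0.89). In the delta class it was at 0.45 (−0.38 to 0.99). In clusters 0 and 9 and in the delta class the interval included 0 and 3 of 11 members were lower.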
